A study of Mus musculus with 9 samples.

How the data were processed

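RNA was measured by sequencing in 9 libraries of crypts from the jejunum of mice, 3 in each of 3 groups. The control group is described in 2 ways: the sample labels give its treatment as vehicle, while the design text calls the control mice uninjected. Smad4 KO mice carried floxed Smad4 alleles and Villin-CreER(T2), a tamoxifen-inducible recombinase of the intestinal epithelium. The double mutants carried in addition 1 Ctnnb1 allele whose exon 3 is removed by the recombinase. Loss of that exon removes the phosphorylation sites that mark beta-catenin for degradation. Both mutant groups received tamoxifen on 4 consecutive days and were collected 1 day after the last injection. Crypts were released with 3 mM EDTA and passed through a 70 micron filter, and libraries were made with a TruSeq RNA kit, version 2, per the labels' protocols.

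The deposited values were FPKM, fragment counts scaled by transcript length and by library size, for 23951 genes in each of 2 tables. 1 table held the control and Smad4 KO libraries, and the other held the same controls with the double mutants. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Cuffnorm 2.2.1 and Cuffdiff 2.2.1, and the genome build was mm9; the annotation is not given in the sources used here. The genome supplied for this work was of another build, so no coordinates are printed and genes carry the symbols of the tables. The tables were normalized separately. Between them, the values of each control library differed by a single factor for all genes (1.03, 1.06 and 1.04 for controls 0, 1 and 2). The main tests were therefore made within each table, and the control means printed beside each mutant group come from that group's own table.

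FPKM values hold no read numbers, so the absolute depth is unknown and no counting interval is given. The spacing of low values put the relative depth of the libraries between 0.968 and 1.42 times that of control 0. This estimate carries the scaling of each table as well as depth: control 1 came to 1.07 in the first table and 1.04 in the second. Summed FPKM ran from 568081 to 752340 in the first table and from 573491 to 758719 in the second. The 50 genes with the highest values held between 28.6% and 48.8% of the sum of a library. Some transcripts that all cells use were listed near 0 (Gapdh 0.609 and Ppia 0.451 FPKM on average in the controls), so an exact 0 is reported only as a listed value. The kit does not mark strand, so genes that overlap cannot be told apart by strand.

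Each table was fitted alone with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over its 6 libraries. Empirical Bayes moderation used a mean-variance trend. Tests were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors are standard deviations of FPKM over 3 libraries or standard errors (SE) of the log2 fold change. Labels do not say that the libraries of a group came from separate mice. Each group held libraries of both sexes (below), so none came from a single mouse, but whether every library was from a different mouse is unknown. The p-values therefore measure the spread between these libraries.

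Before the data were examined, 25 gene lists were fixed, of which 23 were tested. The sex-linked list served as a check, and the list of red blood cell and pancreatic or stomach transcripts had fewer than 5 measured members. Lists were tested with camera in limma at its preset correlation between genes of 0.01. The same test with an estimated correlation, camera on ranks and fry were run beside it. Adjusted p-values of lists were computed over the 23 lists. Some lists share members, for example Lgr5 and Axin2 in the Wnt target and stem cell lists, so their results are not independent. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the members of that list.

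The genes to be named were also set before the data were examined. They were Smad4 and Ctnnb1 and up to 6 called genes with the largest change in each direction whose mutant libraries all lay on one side of all controls, leaving out predicted and small RNA genes. From each list that camera called, or with at least 3 called members, up to 3 members with the smallest p were added. The same was done for the SMAD response and Wnt target lists whether called or not. Some genes that the rule chose are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

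Xist and Y-linked transcripts showed that the sexes were mixed: 1 female and 2 male libraries among the controls, and 2 female and 1 male in each mutant group. The script was tested on simulated data with 200 changed genes. For Smad4 KO (11849 genes) it recovered 50.7% of the 2-fold, 86.6% of the 4-fold and 95.5% of the 8-fold changes, with 9 false calls among 164. For the double mutants (11762 genes) it recovered 70.1%, 92.5% and 98.5%, with 2 false calls among 176. The noise was drawn independently for each gene, without shifts shared by the genes of a library. These rates therefore check the script and do not give the power of the real comparisons. Alternatives covered the pseudocount, the filter, the scaling, the variance model, array weights, a replicate block, the fold threshold and leaving out each library. The sex of the mouse as a covariate and leaving out small RNA genes were added after the data were seen.

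A direct test of the double mutants against Smad4 KO had been planned for the case that the control values matched between the tables, which they did not. All 9 libraries were instead joined by median-of-ratios factors and fitted together, as an alternative and for the closing section. Overlap between the comparisons was set beside 100 simulations of unchanged groups that shared 3 control libraries. In these the deviations of all 9 libraries from their group means were reassigned at random, with random signs. Deviations of mutant libraries thus also stood in for controls, so the simulated controls could vary more or less than the real ones.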

Results

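Expression was measured in 9 libraries of jejunal crypts, the proliferative pockets of the intestinal epithelium that hold stem, progenitor and Paneth cells. There were 3 control, 3 Smad4 KO and 3 double-mutant libraries, each group numbered 0 to 2. Smad4 is the shared mediator of BMP and TGF-beta signals. In the double mutants Smad4 was deleted and 1 Ctnnb1 allele was converted to a stabilised form of beta-catenin, the effector of Wnt signalling. Only the mutant mice received tamoxifen and are stated to carry the recombinase, so those 2 factors cannot be separated from genotype. Between 11196 and 11935 genes reached 1 FPKM in a library. The absolute depth is unknown, and the relative depth estimated from low values, which carries the scaling as well, ranged from 0.968 to 1.42 times that of control 0.

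Smad4 transcripts fell in both mutant groups. They were at 49.8 ± 5.02 FPKM in controls and 10.6 ± 0.56 in Smad4 KO crypts (SD, n = 3 each), 21.3% of control. The double mutants had 10.4 ± 0.64 FPKM against 52 ± 5.96 in controls (SD, n = 3 each), 20.1% of control. The log2 fold changes were -2.13 (SE 0.11, limma adjusted p = 0.00664) and -2.21 (SE 0.11, limma adjusted p = 0.00176). All mutant libraries lay below all controls. The exact two-sided permutation p was 0.1 in each comparison, the smallest that 3 against 3 allows. With the sex of the mouse as a covariate the limma adjusted p in Smad4 KO became 0.0553. Ctnnb1, the gene of beta-catenin, was at 315 ± 48.1 FPKM in Smad4 KO (control 291 ± 20.2) and 276 ± 36.8 in the double mutants (control 304 ± 20.8; SD, n = 3 each). Its log2 fold changes of 0.11 and -0.14 did not pass the test (limma adjusted p = 0.748 and 0.509). Gene-level FPKM does not show whether exon 3 was removed.

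**Figure D1:**
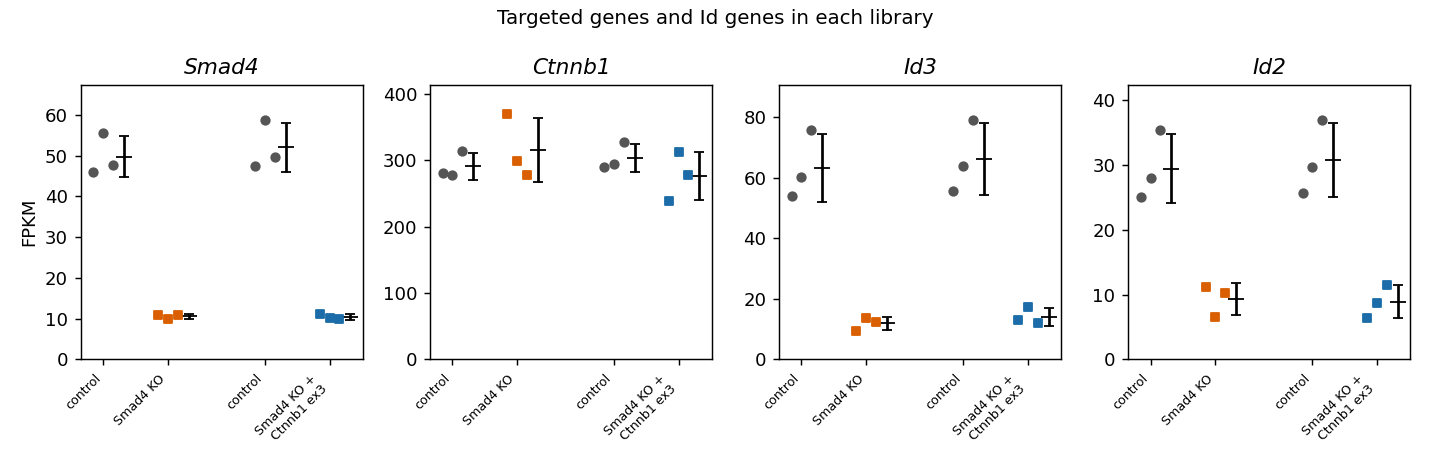
FPKM of Smad4, Ctnnb1, Id3 and Id2 in each library (points), with the mean and SD of 3 libraries beside them (bars); each mutant group stands beside the controls of its own table, and Ctnnb1 ex3 marks the double mutants. Smad4 and Id3 lay below every control in all mutant libraries, and Ctnnb1 overlapped the controls.

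The first comparison asked what loss of Smad4 changed in the crypts. Id3, a transcriptional inhibitor that BMP signalling induces, fell to 11.9 ± 2.14 FPKM in Smad4 KO from 63.3 ± 11.2 in controls (SD, n = 3 each; log2 fold change -2.32, SE 0.18, limma adjusted p = 0.0444). Besides Smad4 and Id3, the other 2 genes that passed were small RNA genes, chosen after their values were seen. Mir26b was listed at 82, 78.8 and 57.1 FPKM in controls 0, 1 and 2 and at 0 in each Smad4 KO library. Mir6386 was listed at 0 in each control and at 71.7, 32 and 80.8 FPKM in Smad4 KO 0, 1 and 2. Mir26b lies within Ctdsp1, so its reads may not be separable from those of its host, which was at 50.2, 60 and 57 FPKM in controls and 36.2, 45.1 and 45.1 in Smad4 KO. In all, 1 gene was higher and 3 were lower of 11849 tested with limma, while 2264 had an unadjusted p below 0.05 (1157 higher, 1107 lower). The 3 Smad4 KO libraries lay outside the range of the controls for 26.4% of genes, against 10% by chance. That 10% is an average over all ways to split the libraries. Genes of a library vary together, so a single split can exceed it, and the share in other splits was not measured.

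The split of higher and lower calls in Smad4 KO varied with the scaling: 2 and 3 with median-of-ratios factors, 4 and 4 with quantile normalization, and 4 and 3 without the 50 highest genes. With all 9 libraries joined in one fit, which pools the spread of the 3 groups, they were 240 and 178. Without 1 library, higher and lower genes numbered 8 and 8 (control 0), 2 and 8 (control 1), 2 and 3 (control 2), 8 and 7 (Smad4 KO 0), 5 and 3 (Smad4 KO 1) and 7 and 3 (Smad4 KO 2). Smad4 and Mir26b passed limma in all 6 of these fits. Id3 had a limma adjusted p of 0.142 without control 1, 0.113 without control 2, 0.0708 without Smad4 KO 1 and 0.106 without Smad4 KO 2. It also missed the threshold with pseudocount 5 (0.0603), without a filter (0.0903) and without the mean-variance trend (0.0661). Mir6386 had a limma adjusted p of 0.0663 without control 2, 0.067 with pseudocount 5 and 0.0617 with the sex of the mouse as a covariate.

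Among 13 measured SMAD and BMP/TGF-beta response genes, only Id3 passed in Smad4 KO, and 2 were higher and 4 lower when adjusted over the list alone. Id2 was at 9.31 ± 2.43 FPKM against 29.4 ± 5.35, and Id1 at 25.1 ± 3.88 against 45.7 ± 7.86 (SD, n = 3 each; log2 fold changes -1.58 and -0.83, limma adjusted p = 0.106 and 0.124). Camera did not call the list (median -0.04, mean -0.30, adjusted p = 0.291). Fry did not call it directionally (adjusted p = 0.0672) but called it for change in either direction (adjusted p = 0.00397). The 19 BMP/TGF-beta pathway components had no called member and a median of -0.10, while their mean was 0.03 (camera adjusted p = 0.61). The 22 Wnt/beta-catenin target genes had no called member (median 0.04, camera adjusted p = 0.739). Of these, the receptor Fzd7 was at 9.16 ± 2.11 against 5.02 ± 0.418 FPKM, Cd44 at 28.7 ± 13.2 against 12.8 ± 3.79, and Ephb2 at 27.7 ± 3.43 against 21.3 ± 3.97 (SD, n = 3 each). The 29 intestinal stem cell markers were not called (median -0.01, camera adjusted p = 0.931).

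Camera called 12 of the 23 lists in Smad4 KO, 7 higher and 5 lower. None was called with an estimated correlation (limma's camera, adjusted p = 0.778 for each of the 12), and fry called 0 directionally and 7 for change in either direction. Another split of the same 6 libraries gave 13 called lists. Apart from Smad4 itself, no member of these 12 lists passed limma over all genes.

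All 27 ribosome biogenesis genes were higher in Smad4 KO, with a median of 0.53 (camera adjusted p = 3.7e-14, and adjusted p = 0.778 with an estimated correlation). Over all genes 0 passed, and 15 were higher when adjusted over the list alone. Ppan, a nucleolar factor of the large ribosomal subunit, was at 54.4 ± 4.95 FPKM against 25.8 ± 3.34, Rrp9 at 28.2 ± 1.28 against 17.7 ± 0.928, and Mrto4 at 16.6 ± 1.09 against 9.5 ± 1.14 (SD, n = 3 each). Of 35 cell cycle and DNA replication genes, 31 had a positive change (median 0.25, camera adjusted p = 0.000789, and adjusted p = 0.778 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 33.3 ± 2.17 against 21.5 ± 0.854 FPKM, Ccne1 at 13.4 ± 1.48 against 9.03 ± 1.87, and Cdc6 at 5.73 ± 1.02 against 3.9 ± 0.363 (SD, n = 3 each). The cell cycle median was 0.13 without control 2 and 0.10 without Smad4 KO 1, where the call ended (camera adjusted p = 0.0674 and 0.131). It was 0.40 without control 1 and 0.45 without Smad4 KO 0.

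Of 24 p53 target genes, 19 had a positive change in Smad4 KO (median 0.63, camera adjusted p = 0.000223, and adjusted p = 0.778 with an estimated correlation). Adjusted over the list alone, 3 were higher and 1 lower. Aen was at 20.6 ± 3.87 FPKM against 8.28 ± 1.33, Gtse1 at 20 ± 7.37 against 6.74 ± 0.954, and Phlda3 at 11.5 ± 11 against 0.351 ± 0.183 (SD, n = 3 each). The list mean of Smad4 KO 0 was 1.49 above the control mean, against 0.25 and 0.34 in Smad4 KO 1 and 2, and the median was 0.23 without Smad4 KO 0. The 14 fetal and regenerative epithelium genes had a median of 1.05 (camera adjusted p = 0.00172, and adjusted p = 0.778 with an estimated correlation). Among them Clu was at 13.2 ± 8.22 against 2.73 ± 1.04 FPKM, Cyr61 at 2.9 ± 1.37 against 0.964 ± 0.0489, and Krt7 at 121 ± 17.8 against 85.7 ± 16.2 (SD, n = 3 each). That call ended without Smad4 KO 0 (median 0.66, camera adjusted p = 0.0559).

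The 24 enteroendocrine cell markers had a median of 0.49, with 4 higher adjusted over the list alone (camera adjusted p = 5.08e-05, and adjusted p = 0.778 with an estimated correlation). The peptide hormone gene Pyy was at 31.1 ± 12.9 FPKM against 4.18 ± 2.44, Tac1 at 29.2 ± 3.78 against 17.4 ± 1.91, and Insm1 at 3.49 ± 0.727 against 1.68 ± 0.145 (SD, n = 3 each). Immediate early and heat shock genes had a median of 0.41 over 19 members (camera adjusted p = 0.0015, and adjusted p = 0.778 with an estimated correlation). Ier2 was at 41.9 ± 4.41 against 26.8 ± 2.36 FPKM, Egr1 at 14.8 ± 11.1 against 2.94 ± 1.19, and Hspa1b, whose reads may be shared with its near-identical copy Hspa1a, at 16.6 ± 5.47 against 4.69 ± 3.14 (SD, n = 3 each). This call ended without Smad4 KO 0 (median 0.41, camera adjusted p = 0.0559), and the median was 0.65 without Smad4 KO 1. The 24 cholesterol synthesis genes had a median of 0.39, with 4 higher adjusted over the list alone (camera adjusted p = 0.000121, and adjusted p = 0.778 with an estimated correlation), and a median of 0.60 without control 0. Insig1, a sterol-responsive regulator, was at 30 ± 1.02 against 16.8 ± 2.79 FPKM (SD, n = 3 each).

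All 42 enterocyte brush border and nutrient absorption genes were lower on average in Smad4 KO, with a median of -1.0 and 0 called (camera adjusted p = 2.13e-06, and adjusted p = 0.778 with an estimated correlation). The bile acid exporter genes Slc51a and Slc51b were at 37.4 ± 21.5 against 112 ± 49 FPKM and 22.5 ± 13 against 61.8 ± 19.9, and the amino acid transporter Slc7a9 at 44.2 ± 27.1 against 108 ± 43.1 (SD, n = 3 each). The libraries did not move together: the list mean was 0.35 above the control mean in Smad4 KO 0, and -2.10 and -1.64 in Smad4 KO 1 and 2. The median was -1.81 without Smad4 KO 0, -0.66 without Smad4 KO 1 and -0.54 without control 2. The 25 enterocyte transcription factors, which include Smad4, had a median of -0.33 and were called (camera adjusted p = 5.96e-05, and adjusted p = 0.778 with an estimated correlation). Without Smad4 among its members the median was -0.32, and with it -0.50 when control 0 was left out. Maf was at 6.96 ± 5.63 against 38.4 ± 14.8 FPKM and Ppard at 36.5 ± 4.47 against 63.6 ± 5.57 (SD, n = 3 each).

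**Figure D2:**
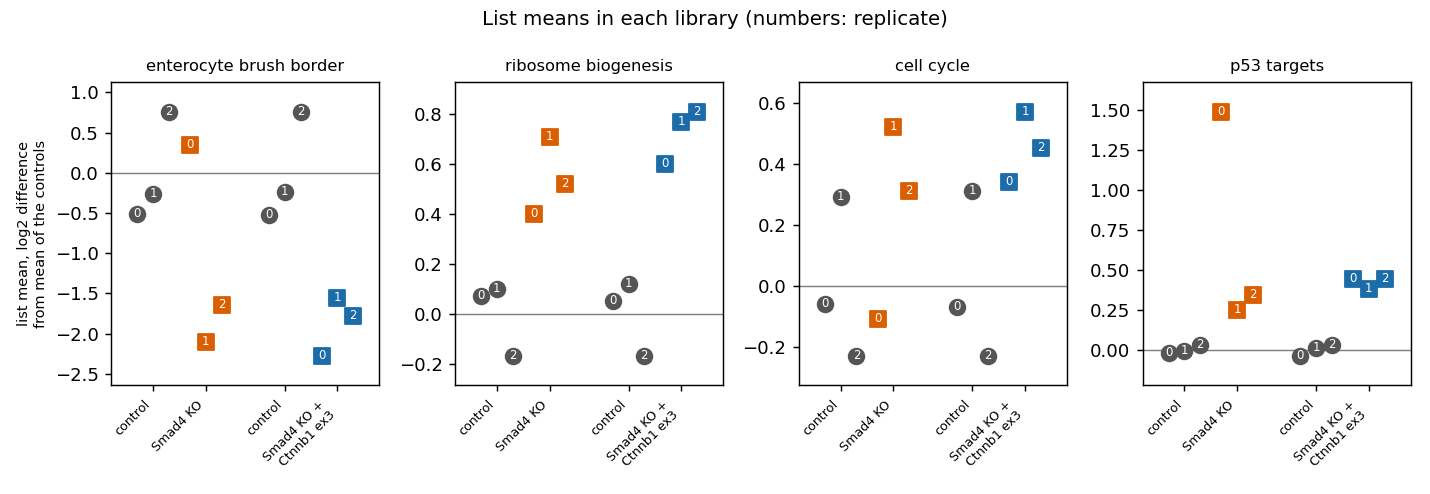
Mean of 4 gene lists in each library as the log2 difference from the mean of the controls; each point is 1 library, the number inside it is the replicate, and Ctnnb1 ex3 marks the double mutants. Smad4 KO 0 lay at 0.35 for the enterocyte list and 1.49 for the p53 targets, away from Smad4 KO 1 and 2.

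Fatty acid oxidation and PPAR target genes (27 members, median -0.46, camera adjusted p = 0.000123, and adjusted p = 0.778 with an estimated correlation) were also called lower in Smad4 KO, with a median of -0.29 without control 2. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, was at 19.4 ± 5.72 against 39.7 ± 4.68 FPKM, Hadhb at 8.55 ± 1.35 against 13.3 ± 1.55, and Acadm at 34.6 ± 7.22 against 62.3 ± 13.3 (SD, n = 3 each). Xenobiotic metabolism genes (29 members) had a median of -0.66 (camera adjusted p = 0.00298, and adjusted p = 0.778 with an estimated correlation). The sulfotransferases Sult1d1 and Sult1b1 were at 32.5 ± 10.4 against 111 ± 32.2 FPKM and 25.2 ± 18 against 72.9 ± 33.5, and the cytochrome P450 gene Cyp2b10 at 6.78 ± 9.1 against 25.1 ± 16.1 (SD, n = 3 each). The xenobiotic call ended without control 2 (median -0.33, camera adjusted p = 0.0816), Smad4 KO 1 (-0.46, 0.133) or Smad4 KO 2 (-0.36, 0.126), and the median was -1.25 without Smad4 KO 0. All 20 tuft cell markers were lower on average (median -0.66, camera adjusted p = 2.09e-05, and adjusted p = 0.778 with an estimated correlation), with a median of -0.36 without control 0. Dclk1 was at 4.02 ± 0.981 against 9.4 ± 4.86 FPKM and Siglec5 at 1.75 ± 1.15 against 5.28 ± 2.13 (SD, n = 3 each).

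Several lists were not called in Smad4 KO but were called on leaving out 1 library or under another setting. Paneth cell markers, many of them alpha-defensins whose reads may be shared between copies, had a median of -0.75 over 22 genes (camera adjusted p = 0.11). Their list mean was -3.16 in Smad4 KO 0, -0.28 in Smad4 KO 1 and 1.08 in Smad4 KO 2, and they were called without control 2 (median -1.05, camera adjusted p = 0.0272) or Smad4 KO 2 (-1.73, 3.62e-05), with quantile normalization (-0.91, 0.0291) or with sex as a covariate (-1.26, 0.00686). Mesenchymal, muscle and endothelial markers had a list mean of 1.65 in Smad4 KO 2 (median of 9 genes 0.85, camera adjusted p = 0.295) and were called without Smad4 KO 1 (1.45, 0.00617) or without a filter (0.22, 0.00374). Dcn, a fibroblast proteoglycan, and Hbb-b1, a red blood cell globin, chosen after their values were seen, were at 47.8 and 38.5 FPKM in Smad4 KO 2, and at most 5.13 and 4.52 in the other libraries of the table. The immune cell markers (median of 26 genes -0.28, camera adjusted p = 0.562) were called lower without Smad4 KO 2 (-0.93, 0.027). Interferon response and antigen presentation genes (median of 35 genes 0.13, camera adjusted p = 0.739) were called higher without Smad4 KO 1 (0.55, 0.000274), and goblet cell markers (median of 23 genes 0.09, camera adjusted p = 0.528) without control 0 (0.29, 0.018). Antimicrobial and mucosal defence genes (median of 18 genes -0.23, camera adjusted p = 0.931; adjusted over the list alone 3 were higher and 3 lower) were called lower only among genes with a mean of at least 5 FPKM (-0.59, 0.0163). Oestrogen response genes (9 genes, median -0.05, mean 0.17, test direction down, camera adjusted p = 0.739) were not called.

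The second comparison asked what changed when Smad4 loss was combined with stabilised beta-catenin. In the double mutants 28 of 42 enterocyte brush border genes fell, while 21 of 27 ribosome biogenesis genes, 12 of 35 cell cycle genes and 10 of 24 p53 targets rose and 2 p53 targets fell. Camera called these 4 lists, but not with an estimated correlation (adjusted p = 0.596 for the first 3 and 0.441 for the p53 targets). Fry called the enterocyte, ribosome biogenesis and p53 lists directionally (adjusted p = 0.0372, 0.00956 and 0.000774), but not the cell cycle list (0.085). Sis, the brush border enzyme sucrase-isomaltase, fell to 43 ± 12.4 FPKM from 446 ± 202 (SD, n = 3 each; log2 fold change -3.29, SE 0.37, limma adjusted p = 0.0107). The p53 target Phlda3 rose to 8.02 ± 2.34 FPKM from 0.367 ± 0.191 (SD, n = 3 each; log2 fold change 2.69, SE 0.24, limma adjusted p = 0.00694). The stem cell receptor Lgr5 rose to 16.9 ± 4.12 FPKM from 7.37 ± 1.22 (SD, n = 3 each; log2 fold change 1.08, SE 0.19, limma adjusted p = 0.0203). Of 11762 genes tested, limma called 1104 higher and 1069 lower, of which 131 and 379 differed at least 2-fold. The libraries of the double mutants also varied less, with a median SD of 0.145 on the log2 scale against 0.213 in Smad4 KO. The numbers of called genes therefore do not compare the sizes of the effects in the mutant groups. The mutant libraries lay outside the range of the controls for 42.6% of genes, against 10% by chance as an average over all splits. The share in other splits was not measured here either.

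Those counts depended on each library. Without 1 library, higher and lower genes numbered 657 and 898 (control 0), 688 and 487 (control 1), 533 and 531 (control 2), 78 and 61 (double mutant 0), 338 and 370 (double mutant 1) and 18 and 12 (double mutant 2). Of the 64 called genes named by the rule, 44 were not called without double mutant 0, 20 without double mutant 1 and 57 without double mutant 2. Those counts were 6, 14 and 10 without controls 0, 1 and 2. Smad4, Id3, Etv4, Phlda2, R3hdml, Klf6 and Slc28a1 passed limma in all 6 fits. Other settings ended the call of 9 of these genes (no filter), 7 (sex of the mouse as a covariate), 2 (pseudocount 5), 2 (rescaled without the 50 highest genes), 1 (array weights) and 1 (no mean-variance trend). Array weights gave 1919 higher and 1801 lower genes, and without a filter 621 were lower.

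Among genes with no small RNA or predicted symbol, the largest increases besides Phlda3 were in Mpp3, a membrane scaffold gene (7.76 ± 1.08 FPKM against 0.912 ± 0.616), R3hdml (5.04 ± 1.03 against 0.327 ± 0.109), the imprinted gene Phlda2 (9.01 ± 1.81 against 1.23 ± 0.204) and the ETS transcription factor Etv4 (6.73 ± 1.08 against 0.851 ± 0.235; SD, n = 3 each). Their log2 fold changes ran from 2.06 to 2.24 (limma adjusted p = 0.00694 for R3hdml, Phlda2 and Etv4, and 0.0106 for Mpp3). Ugt1a6b, which shares exons with other Ugt1a genes and is therefore uncertain, rose to 13.4 ± 11.5 FPKM from 1.9 ± 0.534 (SD, n = 3 each; limma adjusted p = 0.0414), with 26.7 FPKM in double mutant 0. Its call ended on leaving out any of the 6 libraries, with a limma adjusted p of up to 0.0901 (without control 0).

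Among genes with no small RNA or predicted symbol, the largest decreases besides Sis were as follows. Slc28a1, a nucleoside transporter, fell to 0.308 ± 0.103 FPKM from 17.4 ± 3.15 (SD, n = 3 each; log2 fold change -3.80, SE 0.16, limma adjusted p = 0.00133). The sphingomyelin-digesting enzyme Enpp7 fell to 7.21 ± 6.11 from 99.1 ± 58.5 FPKM, the peptide transporter Slc15a1 to 6.31 ± 3.64 from 81.6 ± 50.8, and monoamine oxidase B, Maob, to 3.63 ± 1.27 from 51.6 ± 30.7 (SD, n = 3 each). Slc5a4a, which has a near-identical copy and is uncertain, fell to 0.144 ± 0.0634 from 30.8 ± 27.5 FPKM (SD, n = 3 each; log2 fold change -4.43, SE 0.58, limma adjusted p = 0.0127).

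Camera called 14 of the 23 lists in the double mutants, 7 higher and 7 lower. With an estimated correlation 0 were called, the smallest adjusted p being 0.441 for the p53 targets, against 4310 single genes at an unadjusted limma p below 0.05. Fry called 6 lists directionally and 18 for change in either direction. The 6 were the p53 targets, ribosome biogenesis, the enterocyte brush border, the enterocyte transcription factors, and the SMAD and oestrogen response genes. Another split of the same 6 libraries also gave 14 called lists. The counts of called members given below stand beside 2173 called genes among all 11762 tested. A few called members in a list are therefore not an excess by themselves.

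Of 42 enterocyte brush border and nutrient absorption genes, 28 fell and 0 rose, and 40 were lower when adjusted over the list alone. The median was -1.74 (camera adjusted p = 1.82e-16, and adjusted p = 0.596 with an estimated correlation), and the list mean was -2.28, -1.56 and -1.78 in double mutants 0, 1 and 2. Besides Sis, Apoc2 fell to 68.7 ± 2.61 from 164 ± 7.39 FPKM and Slc51b to 11.2 ± 1.46 from 64.6 ± 20.8 (SD, n = 3 each; limma adjusted p = 0.00676 and 0.00832). Of 25 enterocyte transcription factors 8 fell, including Smad4 itself (median -0.47, camera adjusted p = 0.000154, and adjusted p = 0.596 with an estimated correlation). Without Smad4 among its members the median was -0.46. Maf fell to 3.64 ± 0.955 from 40.2 ± 15.6 FPKM and Ppard to 38.4 ± 2.43 from 66.4 ± 6.3 (SD, n = 3 each).

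Fatty acid oxidation and PPAR target genes fell for 10 of 27 members and rose for 1, Acot1, chosen after its values were seen (median -0.71, camera adjusted p = 7.65e-07, and adjusted p = 0.596 with an estimated correlation). Adjusted over the list alone, 14 were lower and 1 higher. Ehhadh fell to 16.2 ± 2.21 from 41.5 ± 5.21 FPKM, Hadhb to 8.39 ± 0.884 from 13.9 ± 1.72, and the fatty acid transporter Cd36 to 0.52 ± 0.219 from 9.44 ± 6.05 (SD, n = 3 each). Xenobiotic metabolism genes fell for 15 of 29 members, or 24 adjusted over the list alone (median -1.17, camera adjusted p = 7.4e-08, and adjusted p = 0.596 with an estimated correlation). Sult1d1 fell to 20.7 ± 3.61 from 116 ± 34.9 FPKM, Sult1b1 to 13.7 ± 3.55 from 76.2 ± 35.1, and Cyp2b10 to 1.89 ± 1.16 from 26.2 ± 16.8 (SD, n = 3 each).

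All 27 ribosome biogenesis genes had a positive change in the double mutants, of which 21 rose, or 27 adjusted over the list alone (median 0.72, camera adjusted p = 7e-14, and adjusted p = 0.596 with an estimated correlation). Nop56 rose to 69.2 ± 5.49 from 36.5 ± 0.763 FPKM, Rrp9 to 34.5 ± 2.11 from 18.5 ± 0.95, and Rrs1 to 28 ± 2.03 from 14.2 ± 1.2 (SD, n = 3 each). Of 35 cell cycle and DNA replication genes 12 rose and 0 fell, or 14 adjusted over the list alone (median 0.45, camera adjusted p = 1.26e-07, and adjusted p = 0.596 with an estimated correlation). The mitotic kinase gene Plk1 rose to 51.9 ± 1.38 from 28.9 ± 4.43 FPKM, Rrm2 to 38.4 ± 3.32 from 22.5 ± 1.16, and Cdc6 to 6.99 ± 0.432 from 4.07 ± 0.406 (SD, n = 3 each).

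Among 22 Wnt/beta-catenin target genes 4 rose and 1 fell, with the same counts adjusted over the list alone (median 0.31, camera adjusted p = 0.00751, and adjusted p = 0.606 with an estimated correlation). Lgr5, Fzd7 (9.65 ± 1.16 against 5.24 ± 0.51 FPKM), Cd44 (29.3 ± 1.13 against 13.3 ± 3.99) and the cyclin gene Ccnd1 (102 ± 11.5 against 69.7 ± 7.45) rose, and Prr15 fell (14 ± 4.82 against 38.9 ± 14.1; SD, n = 3 each). Axin2, a feedback inhibitor of Wnt signalling, was at 33.2 ± 5.99 against 30.9 ± 6.64 FPKM (SD, n = 3 each; limma adjusted p = 0.724). Ccnd1, Prr15 and Axin2 were chosen after their values were seen. Of 29 intestinal stem cell markers 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.00751, and adjusted p = 0.618 with an estimated correlation). Smoc2 rose to 97.5 ± 8.17 from 56 ± 5 FPKM and Lrig1 to 51.8 ± 2.71 from 33.5 ± 3.73, while Vdr, the vitamin D receptor, also chosen after its values were seen, fell to 51 ± 10.7 from 127 ± 29.7 (SD, n = 3 each). Without control 2 the medians were 0.12 for the Wnt targets and 0.15 for the stem cell markers.

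Of 13 SMAD and BMP/TGF-beta response genes 3 fell and 1 rose, or 4 and 2 adjusted over the list alone, and camera did not call the list (median -0.06, adjusted p = 0.254), while fry did so directionally (adjusted p = 0.00537). Id3 fell to 14 ± 2.87 from 66.1 ± 11.9 FPKM, Id2 to 8.91 ± 2.54 from 30.7 ± 5.66 and Id1, chosen after its values were seen, to 30.8 ± 2.03 from 47.7 ± 8.41 (SD, n = 3 each). Pmepa1, a TGF-beta-induced gene, rose to 6.81 ± 0.375 from 3.27 ± 0.86 FPKM. Of 19 BMP/TGF-beta pathway components (median -0.14, camera adjusted p = 0.389), the receptor gene Tgfbr2 rose to 6.98 ± 0.901 from 3.21 ± 0.55 FPKM, while Bmp2 fell to 1.72 ± 0.099 from 3.26 ± 0.29 and Smad1 to 21 ± 1.99 from 29.3 ± 2.77 (SD, n = 3 each). Smad1 was not called on leaving out any of the 6 libraries, with a limma adjusted p of up to 0.145 (without double mutant 2).

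Of 24 p53 target genes 10 rose and 2 fell, or 12 and 2 adjusted over the list alone (median 0.35, camera adjusted p = 0.00158, and adjusted p = 0.441 with an estimated correlation). The list was not called among genes with a mean of at least 5 FPKM (median 0.10, camera adjusted p = 0.161). Bax rose to 105 ± 5.46 from 52.6 ± 2.94 FPKM and Gtse1 to 20.4 ± 0.875 from 7.05 ± 1.05 (SD, n = 3 each). Sesn1 and Pmaip1 fell, to 15.9 ± 0.691 from 48.8 ± 15.9 and 7.09 ± 0.657 from 11.7 ± 1.9 FPKM, and Cdkn1a was at 61.6 ± 6 against 64.5 ± 10 (SD, n = 3 each); these genes were chosen after their values were seen. Of 18 immediate early and heat shock genes 5 rose and 1 fell, with the same counts adjusted over the list alone (median 0.32, camera adjusted p = 0.0459, and adjusted p = 0.596 with an estimated correlation). Egr1 rose to 11.7 ± 2.1 from 3.09 ± 1.28 FPKM, and the transcription factor gene Klf6 fell to 15.3 ± 1.17 from 34.4 ± 0.272 (SD, n = 3 each). This call ended without control 1 (median 0.22, camera adjusted p = 0.12) or double mutant 0 (0.36, 0.0545), with sex as a covariate (0.30, 0.119) or among genes with a mean of at least 5 FPKM (0.36, 0.0588), and the median was 0.53 without control 2. Cholesterol synthesis genes (24 members, 2 risen, 0 adjusted over the list alone, median 0.40, camera adjusted p = 0.00751, and adjusted p = 0.626 with an estimated correlation) included Pmvk, which did not pass, at 32.3 ± 3.8 against 21.7 ± 3.78 FPKM (SD, n = 3 each). Their call ended without control 1 (0.32, 0.064) or double mutant 1 (0.24, 0.0962) and with array weights (0.15, 0.396), and the median was 0.25 without control 2.

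Immune cell markers fell for 10 of 22 members, or 11 with 1 higher adjusted over the list alone (median -1.10, camera adjusted p = 0.000187, and adjusted p = 0.606 with an estimated correlation). Among the genes that fell were Ccl5 (28.2 ± 11.6 against 130 ± 46.9 FPKM), Cd3g (3.1 ± 0.834 against 12.8 ± 5.41) and Nkg7 (5.07 ± 1.64 against 18.1 ± 5.55; SD, n = 3 each). Tuft cell markers fell for 4 of 20, also adjusted over the list alone (median -0.81, camera adjusted p = 5.05e-05, and adjusted p = 0.606 with an estimated correlation), with Ptpn6 at 10.2 ± 1.23 against 18 ± 1.86 FPKM and Alox5 at 1.38 ± 0.971 against 6.44 ± 3.13 (SD, n = 3 each). The tuft median was -0.53 without control 0. Interferon response and antigen presentation genes fell for 3 of 33, or 1 adjusted over the list alone (median -0.23, camera adjusted p = 0.0179, and adjusted p = 0.639 with an estimated correlation), with Ifit1 at 1.56 ± 0.359 against 5.33 ± 1.53, Irf7 at 15.4 ± 1.96 against 30.3 ± 8.99 and Usp18 at 1.89 ± 0.457 against 7.85 ± 4.73 FPKM (SD, n = 3 each). That call ended without control 0 (median -0.17, camera adjusted p = 0.153) or control 2 (-0.12, 0.119), and among genes of at least 5 FPKM (-0.23, 0.06), and the median was -0.48 without control 1.

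The remaining lists were not called in the double mutants, though some were under another setting. The 17 antimicrobial and mucosal defence genes had a median of -0.64 (camera adjusted p = 0.187) and were called among genes with a mean of at least 5 FPKM (-1.15, 0.00902) or with array weights (-0.96, 0.0498), with Reg1 fallen to 12.5 ± 4.37 from 111 ± 60.6 FPKM, the chemokine Ccl25 to 132 ± 26.7 from 449 ± 178, and Ltf risen to 2.22 ± 0.535 from 0.454 ± 0.0217 (SD, n = 3 each). Of 25 enteroendocrine cell markers 3 rose (median 0.25, camera adjusted p = 0.0734), namely Pyy (18.5 ± 3.87 against 4.35 ± 2.53 FPKM), Insm1 (3.38 ± 0.661 against 1.76 ± 0.154) and Neurog3, the transcription factor that specifies this lineage (10.5 ± 2.86 against 4.73 ± 0.0814; SD, n = 3 each). That list was called without control 2 (0.37, 0.0134) or double mutant 1 (0.32, 0.00555), without a filter (0.23, 0.0285) or with array weights (0.56, 0.00283). The 14 fetal and regenerative epithelium genes had a median of 0.52 (camera adjusted p = 0.072), with 1 risen, Areg (4.51 ± 0.992 against 1.1 ± 0.51 FPKM), and 1 fallen, Il33, chosen after its values were seen (2.17 ± 0.574 against 5.34 ± 1.71; SD, n = 3 each). They were called without control 2 (0.43, 0.0443), double mutant 1 (0.47, 0.034) or double mutant 2 (0.53, 0.0357), or without a filter (0.36, 0.0221). Paneth cell markers had a median of -0.51 over 22 genes and no call (camera adjusted p = 0.118), but were called without control 2 (-0.87, 0.0235) or double mutant 0 (-1.18, 0.00144), with quantile normalization (-0.45, 0.0345) or with array weights (-0.89, 0.00934). Goblet cell markers (median of 23 genes 0.05, mean -0.03, camera adjusted p = 0.821) had 1 fallen member. Oestrogen response genes (median of 9 genes 0.02, camera adjusted p = 0.821, called directionally by fry with an adjusted p of 0.00537) included Areg and Ltf risen and Pdzk1 fallen, to 8.19 ± 1.84 from 34.9 ± 16.3 FPKM (SD, n = 3 each). Mesenchymal, muscle and endothelial markers (median of 7 genes 0.01, test direction down, camera adjusted p = 0.821) had a list mean of 1.27 in double mutant 0, where Dcn was at 27.2 and Hbb-b1 at 26.1 FPKM, against at most 0.921 and 4.67 in the other libraries of that table.

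**Figure D3:**
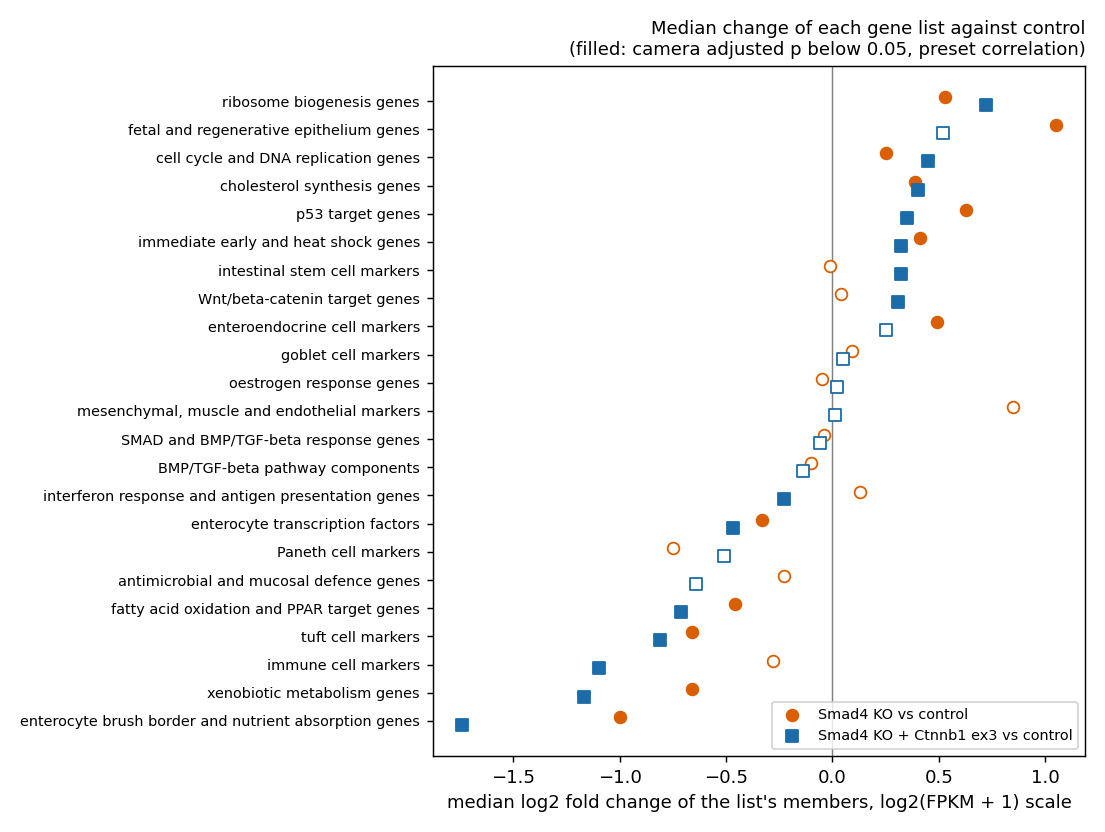
Median log2 fold change of the members of each of 23 gene lists in Smad4 KO (circles) and in the double mutants (squares, Ctnnb1 ex3) against control, on the log2(FPKM + 1) scale; filled symbols had a camera adjusted p below the threshold at the preset correlation. The enterocyte brush border list lay lowest in both, at -1.0 and -1.74.

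Both comparisons used the same 3 control libraries. Of 11662 genes tested in both, 4 were called in both with the same direction, namely Smad4, Id3, Mir26b and Mir6386. Independent lists would share 0.0944 higher and 0.275 lower genes, and 100 simulations of unchanged groups with shared controls gave an overlap of 0 on average. Such groups hold no changed genes, so that overlap does not show what shared controls add among called genes. Among the 4, Smad4 was deleted by design in both groups. Across genes, which are not independent replicates, the fold changes correlated with r = 0.796, against a simulated mean of 0.441 and 95th percentile of 0.849. Their covariance was 0.343 against a simulated mean of 0.108 and 95th percentile of 0.226, a difference of 0.235 from the mean. All 2170 genes called in the double mutants and tested in both had the same sign in Smad4 KO; as many top genes of the simulations did so for 75.3% on average, with a 95th percentile of 99.96%. Part of this may come from the shared controls, which are too few to be split. Without 1 library the number called in both was 11 (control 0), 7 (control 1) and 10 (Smad4 KO 0), and with the 9 libraries joined in one fit it was 410. A difference between the mutant groups was not tested here, because their tables were normalized separately.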

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

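All tests of explanations in this part were chosen only after the result was seen, and the test of the lists that differ between the genotypes was revised after its outcome was seen, while joining the 9 libraries in one fit was planned. In that fit 16 of 23 gene lists differed between the double mutants and Smad4 KO by camera at its preset correlation, and this difference between groups is why they are given here. The medians, double mutant minus Smad4 KO, were 0.24 for Wnt/beta-catenin targets, 0.35 for intestinal stem cell markers, 0.23 for cell cycle and DNA replication and 0.21 for ribosome biogenesis. They were -0.49 for fetal and regenerative epithelium genes, -0.68 for the enterocyte brush border, -0.21 for enteroendocrine markers, -0.09 for tuft cell markers and -0.52 for immune cell markers. They were -0.40 for mesenchymal markers, -0.27 for p53 targets, -0.14 for immediate early genes, -0.34 for interferon response, -0.43 for antimicrobial defence, -0.18 for fatty acid oxidation and -0.53 for xenobiotic metabolism. With an estimated correlation 0 lists differed. No single gene differed among 11852 tested with limma, and 182 had an unadjusted p below 0.05, against 592.6 that chance alone would give on average. Genes of a library vary together, so a single comparison can fall below that average. The low number therefore does not show that the genotypes are alike. Without Smad4 KO 0, 1 gene was higher and 2 were lower. The unadjusted 95% interval of a gene's difference reached 0.375 to either side in the median, and after adjustment larger differences also went uncalled.

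The differences between the genotypes depended most on Smad4 KO 0, without which 11 of the 16 lists were no longer called and the median size of the differences went from 0.305 to 0.10; other libraries ended calls too, and 4 lists were called in all 6 leave-outs. Of the 16 lists, 7 had a median that changed sign without Smad4 KO 0. Among these the p53 targets (0.11) were called in the opposite direction (camera adjusted p = 0.000409). Outside the 16, Paneth (-0.95, camera adjusted p = 2.02e-10) and goblet cell markers (-0.16, 0.0168) were newly called. The Paneth median had been 0.17 and so also changed sign, while the goblet median had been -0.03. Called in the same direction were the Wnt targets (0.19), stem cell markers (0.17), ribosome biogenesis (0.11) and antimicrobial genes (-0.33). The Wnt and stem cell lists share members, so their calls are not independent. In 1 of the 4 lists called in the same direction all double mutants lay on one side of Smad4 KO 1 and 2. Chance gives this in 20% of cases, so neither Smad4 KO 0 alone nor stabilised beta-catenin could be singled out. Of the 10 ways to split the 6 mutant libraries, 1, the real one, gave as many as 16 lists and another gave 15, and 10 splits are too few for a p below 0.05.

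Camera called the enterocyte list lower and the ribosome biogenesis list higher in both mutant groups, though not with an estimated correlation (adjusted p = 0.778 in Smad4 KO and 0.596 in the double mutants for each). Fry called both directionally in the double mutants (adjusted p = 0.0372 and 0.00956) and neither in Smad4 KO (0.457 and 0.0672). No member of either list passed over all genes in the Smad4 KO group; fewer villus cells in the crypt preparations could produce both patterns by dilution. If dilution raised all crypt transcripts alike, the ribosome biogenesis and cell cycle lists would rise equally. With both mutant groups pooled they were 0.62 and 0.34 above control, a difference of 0.29 (exact permutation p = 0.0119, the smallest that 84 choices of 3 controls allow). That premise was not tested, and the cell cycle list could have moved for other reasons. In Smad4 KO 0, where the gap was largest (0.51), the cell cycle mean was -0.12. The test therefore cannot decide whether dilution was the only cause of the ribosome biogenesis increase. The enterocyte list lay below every control in 5 of 6 mutant libraries (not in Smad4 KO 0), which both fewer villus cells and less differentiation would give, so the 2 remain open.

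Camera called the p53 target list higher in both mutant groups, though not with an estimated correlation (adjusted p = 0.778 and 0.441). Fry called it directionally in the double mutants (adjusted p = 0.000774) but not in Smad4 KO (0.39). No member of the 24 passed over all genes in the Smad4 KO group, and Smad4 KO replicate 0 alone could have produced the camera call there. Without that library the list was still called at the preset correlation (median 0.23, camera adjusted p = 0.0116), so the call did not rest on it alone. The list mean lay above every control in 5 of the 5 other mutant libraries, of which only Smad4 KO 1 and 2 bear on the Smad4 KO call. It lay there in 6 of 6 mutant libraries, as tamoxifen or Cre activity, which only mutant mice had, would also give, so an effect of genotype could not be told from one of the treatment.

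Other splits of the libraries of each table show how often such counts arise. In Smad4 KO, 5 of 10 splits called as many genes as the real one (4, against 9 at most), and 6 of 10 as many lists (12, against 13 at most). In the double mutants 1 of 10, the real one, called 2173 genes against 9 at most, and 2 of 10 called 14 lists. The counts of the Smad4 KO fit of 6 libraries could therefore have arisen from a random grouping, though no split reaches a p below 0.05. The joined fit of 9 libraries called 240 genes higher and 178 lower in Smad4 KO, so the gene count depends on the fit.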

How the results depend on the processing

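The sex covariate and leaving out small RNA genes were chosen only after the data were seen; the other alternatives were planned. In the comparisons with control no called list and no called gene among those named changed sign. Among list medians that were not called (over both comparisons), 14 did so under some setting. Without Smad4 KO 0, 7 of the 16 called list differences between the mutant groups changed sign, as did the uncalled Paneth list. Smad4 was lower under all alternatives; in Smad4 KO its adjusted p left the threshold with the replicate block (-2.13, limma adjusted p = 0.234) and the sex covariate (-2.10, limma adjusted p = 0.0553). Id3 and Mir6386 were not called in Smad4 KO with the block either (limma adjusted p = 0.234 each). With the block 5 named genes of the double mutants were not called, and the fetal, Paneth and enteroendocrine lists were (camera adjusted p = 0.0353, 0.0264 and 0.0288). Leaving out 1 library gave -2.18 to -2.05 in Smad4 KO and -2.27 to -2.12 in the double mutants. Where values moved, the cause was not tested.

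Higher genes in Smad4 KO (1) became 3 with pseudocount 0.1, 0 with pseudocount 5, 2 at a mean FPKM of at least 5, 2 with median-of-ratios rescaling, 4 with quantile normalization, 4 without the 50 highest genes, 2 with robust empirical Bayes, 4 with array weights, 0 with the replicate block, 0 with the sex covariate and 2 without small RNA genes; leaving out 1 library gave 2 to 8. Lower genes (3) became 1 with the replicate block and 3 to 8 on leaving out 1 library. In the double mutants, higher genes (1104) became 1919 with array weights, 732 with the replicate block, 131 at an absolute log2 fold change of at least 1 and 18 to 688 on leaving out 1 library. Lower genes (1069) became 621 without a filter, 1801 with array weights, 379 at an absolute log2 fold change of at least 1 and 12 to 898 on leaving out 1 library.

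Called lists (12 and 14) became 0 and 0 with an estimated correlation and 0 and 6 with fry; leaving out 1 library gave 10 to 13 and 12 to 16. Genes called in both (4) became 2 with pseudocount 5, 8 with quantile normalization, 7 without the 50 highest genes, 7 with array weights, 1 with the replicate block, 2 with the sex covariate and 410 with the 9 libraries joined; leaving out 1 library gave 3 to 11. In that joined fit 240 genes were higher and 178 lower in Smad4 KO, and 894 and 747 in the double mutants.

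Replicate numbers were not taken to pair the libraries: correlations of deviations between equal numbers were -0.111, 0.223 and -0.099 in Smad4 KO and 0.072, 0.132 and 0.037 in the double mutants. Each control correlated best with the double mutant of its own number, so pairing in that comparison was not settled. Among the Smad4 KO libraries only number 1 was the best partner of the control of its number. Read numbers were not used here, so the effect of depth on low genes could not be measured.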

Other observations

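The values in this part were chosen only after they were seen, and no explanation was tested for them. Smad4 KO 0 stood apart from the other Smad4 KO libraries in several transcripts. The fatty acid binding protein gene Fabp1 was at 4450 FPKM there, and at 229 and 505 in Smad4 KO 1 and 2 (controls 654, 1020 and 2030). The cell cycle inhibitor Cdkn1a was at 241 against 48 and 61.5 FPKM, the growth factor Areg at 36 against 1.01 and 4.08, and the Paneth cell defensin Defa24 at 5150 against 38300 and 52700. The stem cell receptor Lgr5 was at 2.64 FPKM there, and at 9.32 and 19.1 in Smad4 KO 1 and 2.

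The antimicrobial phospholipase gene Pla2g2a differed widely within every group: 20100, 112 and 4640 FPKM in the controls, 38.5, 5910 and 18700 in Smad4 KO, and 9960, 5770 and 171 in the double mutants. The small RNA gene Mir7646 was listed at 10000 FPKM in control 0 and at 0 in the other libraries of the first table. In the double mutants Mir26b was again listed at 0 in each library (controls 84.5, 83.5 and 59.5), and Mir6386 at 26.3, 66.6 and 143 FPKM with 0 in each control.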
